A study of Caenorhabditis elegans with 4 samples.

How the data were processed

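ChIP-seq against GFP was performed on L1 hermaphrodites carrying a GFP-tagged nhr-28 transgene, with 2 ChIP samples and 2 input samples per the labels. Worms were grown on E. coli HB101, crosslinked with 2% formaldehyde and quenched with 100 mM Tris, and chromatin was sheared by sonication, per the labels' protocols. The series text names a growth temperature of 20 °C. The stage label carries the suffix 26 dC, which no source explains, so the temperature of the harvested worms is uncertain if that suffix is a temperature. Samples were grouped by their titles.

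The authors deposited 3 peak lists in GFF version 3 format, for ChIP replicate 1, ChIP replicate 2 and the whole series. Peaks were called with PeakSeq on WormBase build WS220, per the file headers and the source field of each line. PeakSeq scores regions of a ChIP library against a control. Its version, the aligner, the threshold, the control used for each list, any masking of regions, and whether reads were pooled for the series-wide list are not given in the sources used here. Each peak has a start, an end and 1 significance value; it lies between 0 and 0.001 in every list as deposited and is a p-value or q-value, and which of these it is was not stated. It was used only to rank, describe and split peaks within a list, and, for peaks matched between the replicate lists, to correlate their order (Spearman) and their −log10 values (Pearson). Values of the same region in different lists are set side by side only, as the lists were not shown to be on the same scale. No strand, summit, read count or fold enrichment was used. Peak numbers in the names run to 5479 over 5338 entries in the series-wide list (first unfilled number 816). They run to 811 over 806 entries in replicate 1 (first unfilled 786) and to 807 over 803 in replicate 2 (first unfilled 746). The lists used here therefore hold slightly fewer peaks than were numbered. No neighbouring peaks lay closer than 202 bp, 222 bp and 204 bp in these lists.

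A peak was counted as matched when it overlapped another by at least 1 bp. The replicated set holds the series-wide peaks that overlap a peak of both replicate lists. The overlap of the replicate lists was tested against 100000 circular shifts of the replicate 1 list, with an independent offset per chromosome. Rank agreement was tested by permutation with 100000 resamples; values listed at 0 were set to the smallest value above 0 of the list. Chromosome shares were tested with exact binomial tests and differences of shares with Fisher's exact test, both two-sided and, over chromosomes, adjusted by Benjamini-Hochberg with a threshold of 0.05. Intervals are Wilson or exact (Clopper-Pearson) 95% intervals, as named. These tests treat peaks as units and compare these lists; with 2 ChIP samples and no other condition there is no test between groups of samples.

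No genome or annotation of build WS220 was used. The gene table at hand is of assembly WBcel235, a different build, and coordinates were not carried between builds. Peaks are therefore named by position and not by gene, and 5 planned comparisons were not run: location relative to genes, gene lists, sequence words, GC content, and peaks at nhr-28 and unc-119. The chromosome comparison was planned to run only with a reference of the same build. It was run without one, which departs from the plan. Chromosome length was replaced by the largest peak end over the 3 lists (total 100206672 bp), a choice made after the lists were seen. The splits of the lists by significance, the centre distances, replicate support by chromosome and the X share by peak strength were also added then.

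The designs, alternatives and naming rule were set before the data were examined, except those said here or below to be chosen later. For the chromosome shares, 4 alternatives were chosen after the data were seen: the span from first to last peak, each replicate list by itself, and the replicated set without its 100 most significant peaks. The named peaks are the 20 most significant of the replicated set, the 3 most significant unpartnered peaks of each replicate and, given as a range except on X, the next 3 replicated peaks of each chromosome. Alternatives covered the overlap rule, the significance limit, the length of the lists, the placement of shuffled peaks, peak width and each replicate left out. The procedures were tested on simulated data. With lists of 806 peaks placed at random, the overlap test called 0 of 20 pairs of lists, and with 100 planted pairs it called 20 of 20 and found a median of 99.0. With 240 simulated peaks the chromosome test called X in 2 of 200 trials without depletion and in 200 of 200 with X at 0.2 times its expected rate. No weaker deficit and no smaller set was simulated, so the trials do not give the power for the deficits reported below (0.331 times in 240 peaks and 0.567 times in 120). Simulated peaks were placed independently of one another, so these trials do not show how the tests behave where real peaks cluster. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.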

Results

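The binding sites of NHR-28, a member of the nuclear hormone receptor family of transcription factors, were mapped by ChIP-seq in whole Caenorhabditis elegans hermaphrodites at the first larval stage (L1). The worms, of strain OP317, carried an nhr-28 transgene tagged with GFP. The protocol and series text give a growth temperature of 20 °C, while the stage label of every sample also carries the suffix 26 dC, which is not explained. Chromatin crosslinked with 2% formaldehyde was precipitated with antibodies against GFP, and 10% of the chromatin extract was kept as input. The series held 2 ChIP samples and 2 input samples. Peak lists were analysed for ChIP replicate 1, for ChIP replicate 2 and for the series as a whole. The input values were not analysed here. Nothing stated whether the replicates came from separate cultures, so every comparison between them measures only the spread between these 2 samples. All coordinates are on build WS220 and count from 1.

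Replicate 1 held 806 peaks and replicate 2 held 803, while the series-wide list held 5338. The median peak was 227.5 bp wide in replicate 1, 228.0 bp in replicate 2 and 164.0 bp in the series-wide list. Peaks covered 226168 bp in replicate 1 (mean width 281 bp), 230675 bp in replicate 2 (mean width 287 bp) and 1174746 bp in the series-wide list (mean width 220 bp). Each peak had 1 significance value from the authors' peak caller, always 0.001 or less, and smaller values mark stronger peaks. The median value was 0.000193 in replicate 1 and 0.000276 in replicate 2. Read counts per peak were not part of the lists, so the depth behind each peak is unknown, and the intervals given for shares cover counting error only.

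The replicate lists were compared first, to ask which regions were called as peaks in both ChIP samples. As the input values were not analysed here, recurrence of a peak does not by itself show that NHR-28 was bound there. The most significant regions recurred: all of the first 10 peaks of each list had a partner in the other, as did 82 of the first 100 in replicate 1 and 75 of the first 100 in replicate 2. Over whole lists, 234 of the 806 replicate 1 peaks, or 29% (Wilson 95% interval 26.0 to 32.3), overlapped a replicate 2 peak by at least 1 bp. In the other direction 235 of 803 peaks, or 29.3% (26.2 to 32.5), had a partner. Circular shifts of the replicate 1 list within chromosomes gave a mean of 4.42 partnered peaks and a highest value of 68. The observed overlap was 52.9 times the shifted mean (permutation test with 100000 shifts, one-sided p = 1e-05, the smallest that number of shifts can give).

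Partnered peaks were concentrated among the most significant ones. In replicate 1, 66.3% of the most significant 202 peaks had a partner (59.6 to 72.5), against 9.95% of the least significant 201 (6.53 to 14.9). In replicate 2 these shares were 56.7% (49.8 to 63.4) and 11% (7.38 to 16.1).

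**Figure D1:**
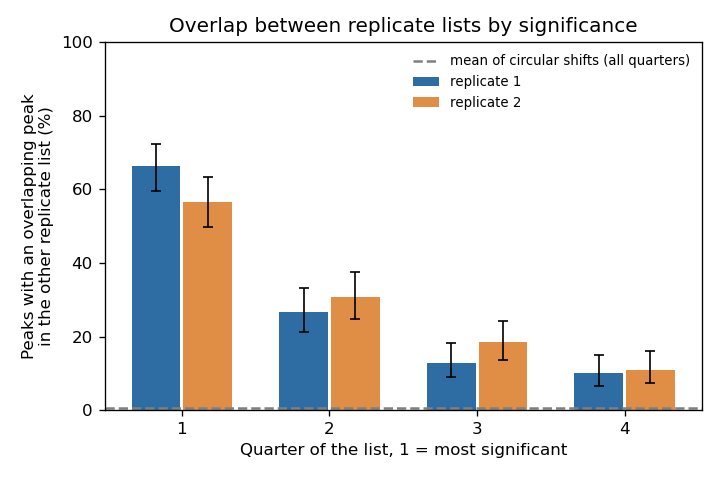
Bars give the percentage of peaks in each replicate list that overlap a peak of the other list by at least 1 bp, with the list ordered by significance and split into 4 equal parts; error bars are Wilson 95% intervals and the dashed line is the mean over circular shifts of the whole replicate 1 list (0.549%). The share falls from 66.3% to 9.95% in replicate 1 and from 56.7% to 11% in replicate 2.

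A set of 233 peaks matched a single peak of the other list and was matched by it alone. Their centres lay a median of 45 bp apart, and 189 of the pairs (81.1%) lay within 100 bp. Across these pairs the order of significance was shared, with Spearman's rho 0.60 and Pearson's r 0.82 on the −log10 scale (permutation tests with 100000 resamples, p = 1e-05 each, the smallest possible; this family held 1 pair of lists). These coefficients run across peaks, which are not independent replicates. Without the top 5% of pairs both fell to 0.53.

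**Figure D2:**
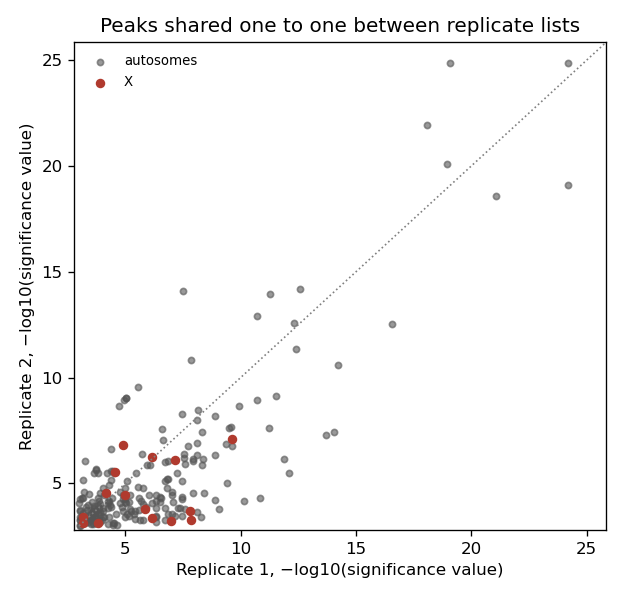
Each point is 1 of the 233 peaks matched singly between the replicate lists, placed by the −log10 of the authors' significance value in replicate 1 (x axis) and replicate 2 (y axis), with X in red and a dotted line of equality; the region listed at 0 in both lists is drawn at the smallest value above 0. Points spread along the diagonal with Spearman's rho 0.60.

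Peaks without a partner reached high ranks in both lists. In replicate 1 the strongest of the 572 unpartnered peaks lay on chromosome I at 13475274 to 13475935 (rank 11, significance 3.84e-14). It was followed by chromosome I at 16670 to 17169 (2.27e-10) and chromosome IV at 654691 to 655261 (1.63e-09). In replicate 2 the strongest of the 568 unpartnered peaks all lay on chromosome II, at 12094555 to 12094984 (rank 21, 1.12e-09), at 6348195 to 6348953 (1.59e-08) and at 12045081 to 12045400 (2.52e-08). Each of these regions was also in the series-wide list.

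The series-wide list was then compared with the replicate lists, to ask how far its peaks rest on each ChIP sample. It contained most replicate peaks: 747 of 806 from replicate 1, or 92.7% (90.7 to 94.3), and 676 of 803 from replicate 2, or 84.2% (81.5 to 86.5), against 3.01% and 3.11% after circular shifts. Both ChIP samples belong to the series that this list covers, so an overlap above that of shifted peaks is not independent agreement. Of the unpartnered replicate peaks, 516 of 572 in replicate 1 and 444 of 568 in replicate 2 were also in it. Seen from the series-wide list, 240 of 5338 peaks, or 4.50% (exact 95% interval 3.96 to 5.09), overlapped a peak of both replicates. A further 502 (9.40%) overlapped replicate 1 alone, 434 (8.13%) overlapped replicate 2 alone, and 4162 (78.0%, 76.8 to 79.1) overlapped neither.

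The peaks found in both replicates were the stronger and wider ones. Their median significance was 9.63e-12 and their median width 488.5 bp, against 0.000125 and 157.0 bp for the other 5098 series-wide peaks. The medians differed by 7.11 on the −log10 scale. A peak enters the first group only if the caller listed it in each replicate, so this difference follows in part from how the groups were formed and no p-value is given. Among the first 534 series-wide peaks by significance, 468 (87.6%) were in at least 1 replicate list and 211 (39.5%) were in both. Among the last 533 these numbers were 11 (2.06%) and 1 (0.188%). The supported share depends on the rule: with only replicate 1 required it was 13.9%, and with only replicate 2 required it was 12.6%.

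The 240 series-wide peaks present in both replicate lists form the replicated set, ranked here by the series-wide value. By that value its strongest member was the last peak listed on chromosome III, at 13778131 to 13781287. It was 3157 bp wide and had a significance of 3.75e-40, with 8.40e-22 in replicate 1 and 2.67e-19 in replicate 2. The next was a region of 2897 bp on chromosome IV at 9053859 to 9056755 (4.90e-38; 7.96e-09 and 1.30e-07 in the replicates). Chromosome I at 9381106 to 9382015 (6.27e-34) and chromosome IV at 2601939 to 2602923 (1.29e-32) followed. Of the first 20 peaks 9 lay on chromosome III, 5 on V, 2 on I, 2 on IV, 1 on II and 1 on X. Their widths ran from 377 to 3157 bp with a median of 925.0 bp. The replicate lists ordered regions differently. Chosen after their values were seen, 4 members of the replicated set outside these 20 ranked among the first 6 of both replicate lists: V at 264904 to 266014, III at 10224453 to 10225339, III at 7446777 to 7447872 and III at 931227 to 931828, in replicate 1 coordinates. Their values ran from 6.82e-25 to 8.62e-19 in replicate 1 and from 1.44e-25 to 8.12e-20 in replicate 2. In the series-wide list they ran from 1.96e-19 to 2.41e-11, and each region had a larger value there than in either replicate list. Most matched peaks went the other way: 32 of 747 in replicate 1 and 41 of 676 in replicate 2 had the smaller value in the replicate list. The lists were not shown to share a scale.

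The other chromosome III members of these 20 had significance values between 4.77e-27 and 1.01e-20. In order of strength they lay at 3867019 to 3867732, 4237603 to 4238165, 3800626 to 3801815, 10758684 to 10759341, 12904842 to 12905352, 8801638 to 8802577, 13643415 to 13643791 and 11444179 to 11445174. On chromosome V the regions were 1627081 to 1627889 (1.72e-24), 18723095 to 18724673 (4.57e-23), 19528851 to 19529530 (2.43e-22), 14200017 to 14200436 (3.03e-22) and 20773327 to 20774542 (1.21e-21). The remaining members lay on X at 13700341 to 13701081 (1.08e-23), on chromosome I at 12039559 to 12040620 (1.26e-22) and on chromosome II at 9112522 to 9113935 (2.45e-22). The next 3 replicated peaks of each chromosome ranged from 1.12e-20, on chromosome II, to 3.21e-16, on chromosome IV. On X these were 8035672 to 8036964 (4.82e-20), 11093779 to 11094409 (4.11e-19) and 14525378 to 14526318 (9.97e-19).

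The distribution of peaks over chromosomes was compared with the length of each chromosome, taken as the largest peak end in any list. Chromosome III was overrepresented and X underrepresented. III held 71 of the 240 replicated peaks, or 29.6% (exact 95% interval 23.9 to 35.8), on 13.8% of the length, which was 2.15 times its expected number (exact binomial test, two-sided, Benjamini-Hochberg adjusted over 6 chromosomes, p = 1.2e-09). X held 14, or 5.83% (3.23 to 9.59), on 17.6% of the length, 0.331 times its expected number (same exact binomial test, adjusted p = 3.0e-07). Per megabase this amounted to 5.15 replicated peaks on III (4.02 to 6.50) and 0.792 on X (0.433 to 1.33). Chromosomes I, II, IV and V held 14.6%, 19.2%, 13.3% and 17.5% of the peaks, and their adjusted p-values were 0.93, 0.16, 0.16 and 0.28. The test treats peaks as independent of one another and uses length as its only background. Differences in gene density, mappability or input signal between chromosomes were not tested, for III as for X.

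Both departures were seen in each list, though the lists are not independent, as the series-wide list contained most peaks of each replicate. X held 22 of 806 peaks in replicate 1 (2.73%, 1.72 to 4.10), 17 of 803 in replicate 2 (2.12%, 1.24 to 3.37) and 185 of 5338 in the series-wide list (3.47%, 2.99 to 3.99). III held 25.6%, 27% and 20.8% in the same order. The exact binomial test gave adjusted p of 1.7e-39, 5.9e-44 and 7.4e-226 for X and 2e-18, 1.7e-22 and 3.3e-44 for III. In the replicated set X held 12 of the 120 more significant peaks (10.0%, 5.27 to 16.8) and 2 of the 120 less significant ones (1.67%, 0.202 to 5.89; Fisher's exact test, two-sided p = 0.011). In the series-wide list the X share did not move in 1 direction with strength. X held 5.06% of its first 534 peaks and 1.31% of the next 534. Over the following parts of 534 or 533 peaks the share went from 2.43% up to 3.93%, down to 3.18% and up to 4.50% in the last 533. That later rise toward weaker peaks was not tested. The first 534 differed from all later peaks (3.29%) with p = 0.045 in Fisher's exact test, two-sided and unadjusted. Taken alone, those 120 stronger peaks did not pass the threshold for X in the exact binomial test (adjusted p = 0.091), whereas III still did (25.8%, adjusted p = 0.0027).

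**Figure D3:**
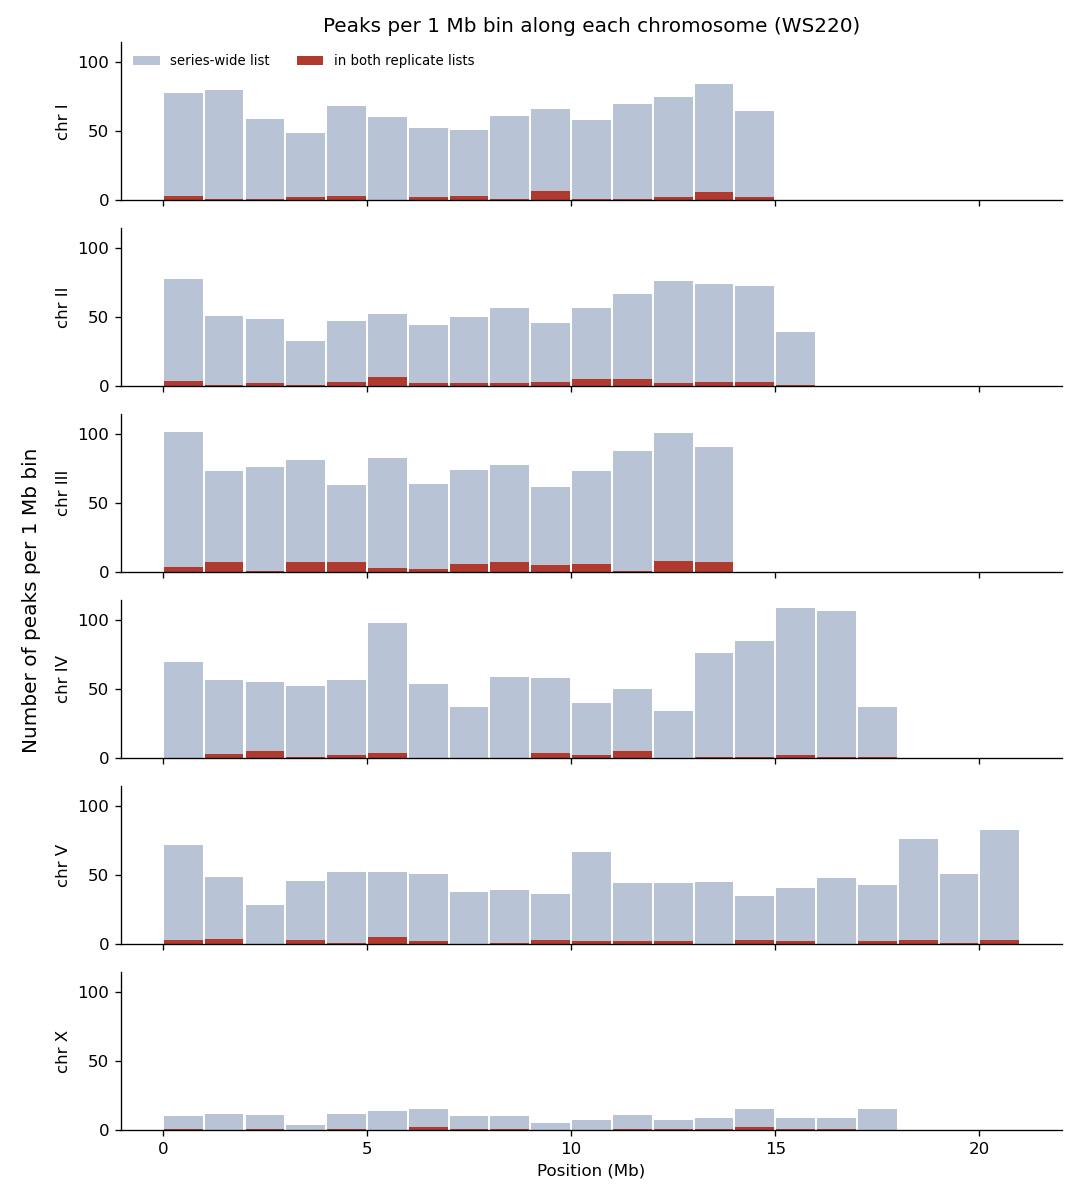
Peaks per 1 Mb bin along the 6 chromosomes on WS220 (x axis, position in Mb; y axis, number of peak centres in the bin), for the series-wide list (grey) and, drawn in front of it from the same baseline, the 240 peaks present in both replicate lists (red). The median bin of the series-wide list holds 77.0 peaks on III and 10.0 on X.

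Replicate support within the series-wide list also varied by chromosome. On III 71 of 1109 peaks (6.40%) were in both replicates against 4.0% elsewhere, and on IV 32 of 1135 (2.82%) against 4.95% elsewhere (Fisher's exact tests, two-sided, Benjamini-Hochberg adjusted over 6 chromosomes, p = 0.0048 for each). Peak strength moved with this difference: 18.8% of the series-wide peaks on III and 11.2% of those on IV had a significance under 1e-06, the highest and the lowest share of any chromosome, and the share in both replicates fell from 39.5% in the first 534 peaks by significance to 2.62% in the next 534. The tests by chromosome did not account for strength. On X the share was 7.57% against 4.39% elsewhere, which did not pass the threshold (Fisher's exact test, adjusted p = 0.093). These shares are of all series-wide peaks, most of which were in neither replicate list. On X, 21 series-wide peaks overlapped a replicate 1 peak, 16 a replicate 2 peak and 14 both. Over all chromosomes these numbers were 742, 674 and 240. The few supported peaks on X were thus more often in both lists, a difference that was not tested.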

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

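The overlap of the replicate lists stayed above the circular shifts under all 8 alternatives, 2 of them chosen after the data were seen (without chromosome III, without peaks under 50 bp), with 24.3% to 37.7% of replicate 1 peaks partnered; the rank agreement stayed positive and past its threshold under 4 alternatives (rho 0.53 to 0.72), of which peak width was chosen later, and the difference in median significance by replicate support was 7.11 on the −log10 scale and 7.14 with 50% reciprocal overlap. The share of series-wide peaks found in both replicates was 4.50% and moved to 3.22% with 50% reciprocal overlap, to 8.80% in the more significant part of the list and to 5.31% without peaks under 50 bp (chosen later); leaving out a replicate gave 12.6% to 13.9%, since only 1 list is then required. The excess on III held under all 9 alternatives (20.8% to 33.6%), 4 of which were chosen after the data were seen, among them the one without the 100 most significant peaks, which gave 33.6%. The deficit on X passed the threshold under 8 of the same 9. In the stronger 120 replicated peaks it was smaller and did not pass (10.0%, exact binomial test, adjusted p = 0.091). Fewer peaks are tested there, and X held 0.567 times its expected number instead of 0.331. II passed above its expected number under 3 of 9 alternatives and V below under 3 of 9, neither having passed in the replicated set. In the whole series-wide list I and IV lay above their expected numbers (18.3% and 21.3%), and IV did so in the replicate 2 list (20.8%), whereas in the replicated set both lay below without passing the threshold; the cause was not tested. The share of peaks in the central part of each chromosome, chosen after the data were seen, was 30.8% in the replicated set and did not pass the threshold; it fell below the expected 33.3% in the whole list (29.1%) and with either replicate left out (26.5% to 29.1%), while the other 3 of the 6 alternatives gave no departure that passed the threshold (50.4% in the central 50% of the length, 32.5% in the stronger 120 and 28.5% with 50% reciprocal overlap). No paired analysis was possible because peak lists were analysed for the ChIP samples alone and the test compares their 2 lists. The 5 planned comparisons left out for want of a genome or annotation of the build were not run under any setting. Depth cannot be read from the lists, so a missing partner does not show that a region was unbound.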

Other observations

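The tests in this part were chosen after the results they concern had been seen, except the comparison of the replicate overlap with circular shifts, which was planned but whose reading here was set afterwards. On chromosome IV the series-wide peaks were unevenly spread. The stretch from 13000001 to 17000000 held 377 peaks, or 94.2 per Mb, against 56.2 per Mb on the rest of IV, and the densest 1 Mb bin of any chromosome in this list, with 109 peaks, started at 15000001. These peaks were found in at least 1 replicate list about as often as others on IV (21% against 19.8%, Fisher's exact test, two-sided p = 0.64), but 1.33% were in both replicates against 3.56% (p = 0.035, unadjusted, for a region picked by its density). Chromosome IV carries large piRNA gene clusters in this species, and their positions on this build were not compared with the peaks. Over all chromosomes 29.1% of the series-wide peaks lay in the central part that makes up 33.3% of the length (exact binomial test, two-sided p = 2.1e-11), with the shares on I to V between 27% and 30.2%, all below the expected value with adjusted p of 0.039 or less, and 29.2% on X (adjusted p = 0.24). In the replicated set the share was 30.8% (exact binomial test, p = 0.45).

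Very narrow peaks were more common in the series-wide list, where 278 peaks (5.21%) were under 10 bp wide, against 19 (2.36%) and 11 (1.37%) in the replicates.

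The leading entry of each kind of list was missing from the other kind. The series-wide list was led by a region of 36756 bp on X at 16343224 to 16379979, listed at 0 and 6.56 times as wide as the next widest peak, and 0 of the replicate lists had a peak in it. Both replicate lists were led by the last region listed on chromosome I, with a value of 0, at 15063997 to 15067640 in replicate 1, which the series-wide list lacked. A shortfall of significance in the other lists and a difference in which regions were kept or removed cannot be told apart: at most 1 of the 99 entries that followed the leading one was unmatched in any of the 3 lists, and at least 98 were matched, but these counts are of other entries, and the lists hold no value above 0.001, so the value of a missing region is not known. An earlier form of the rule read the counts as against a shortfall and in favour of a difference in removal. That rule was changed after the counts were known, and the counts are the same. Peak numbers followed significance over the first 10 entries of each list, and the first unfilled number was 816 series-wide, 786 in replicate 1 and 746 in replicate 2. Further down the order was not strict: series-wide peak 16 (2.35e-22) was slightly more significant than peaks 14 (2.43e-22) and 15 (2.45e-22). Removal after numbering of a region as strong as the leading ones would have left an earlier gap. Removal before numbering stays open. Extra copies of the tagged gene on the transgene remain open for the region on X: the count of 0 replicate lists with a peak there decides nothing while removal stays open, the input was not analysed, and no annotation of this build was used to place nhr-28.

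Most peaks of each replicate list lacked a partner in the other. Random placement is argued against, because 234 replicate 1 peaks were partnered and the highest of the circular shifts gave 68. Whether the samples were related cannot be decided from this. The overlap to be found between lists of unrelated ChIP samples is not known here, and it need not be as low as that of shifted peaks. Peaks close to the significance threshold, called in 1 library and missed in the other, are a candidate explanation for part of the missing partners. In replicate 1, 66.3% of the most significant 202 peaks were partnered against 9.95% of the least significant 201, and the intervals lay apart in both lists. Other causes that act on weak peaks would give the same contrast. Nearness to the threshold does not cover strong unpartnered peaks, such as that at rank 11 in replicate 1 (3.84e-14). Of the first 100 peaks, 82 in replicate 1 and 75 in replicate 2 had a partner. Differences in read depth between the libraries stay open, as the lists give no depth. No biological explanation was tested, since both samples belong to the same group.

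Chromosome X held few peaks. A missing part of X is argued against, because all 18 of its 1 Mb bins held a series-wide peak. A list that reaches down to weak peaks is argued against as the whole cause, because X held 5.06% of the most significant 534 series-wide peaks, with an upper limit of 7.27% against 17.6% of the length; the X share of the stronger 120 replicated peaks was higher, at 10.0%. A loss in a single library is argued against, because the higher of the upper limits over the replicate lists was 4.10%. Differences in gene density, mappability or input signal between X and the autosomes stay open and were not tested, and the groups of the design give no biological contrast for X.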
